A study of Mus musculus with 30 samples.

How the data were processed

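Total RNA from cultured mouse extraocular muscle was measured on Affymetrix A and B arrays at 5 times, with 3 arrays per time and type. Per the labels, a standard Affymetrix protocol was used. The software, the background correction and the summary method are not given in the sources used here, and neither are detection calls. The deposited values are linear intensities, 1 per probe set, and were used as deposited. In every column the mean after leaving out the lowest and highest 2% of values was 500.2 on the A arrays and 500.1 on the B arrays, so the deposited intensities had been scaled array by array and separately for each type. Column medians ranged from 154.7 to 181.5 on the A arrays and from 272.8 to 297.7 on the B arrays. A and B intensities were not set against each other as levels. Because each array was scaled to a fixed mean, a change in total RNA per cell cannot be seen, and every change is relative to the array.

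Probe sets were named through the platform annotation table supplied with the data, with symbols brought to those of the mouse reference gene table by Entrez identifier. On the A arrays 20393 probe sets had 1 symbol, 691 several and 1606 none, and 20364 matched the reference table. On the B arrays these were 14674, 245, 7656 and 14499. No gene was named from a probe set with several symbols, and no coordinates are given, since the files name no genome build.

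The log2 of intensity plus 16 was analysed without further scaling, so changes of dim probe sets are understated. Control probe sets, 64 per type, and probe sets whose mean over the 15 arrays lay below the 40th percentile (an intensity of 101 on the A and 199.6 on the B arrays) were left out, which left 13577 and 13507 probe sets for 7883 and 6749 genes. A linear model with 1 mean per time was fitted to all 15 arrays of a type with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 10 residual degrees of freedom and prior degrees of freedom of 6.97 and 5.56. P-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. Each of 4 later times was compared with 0 h and each time after 4 h with the preceding one, and an F-test asked for any change over time.

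The gene lists, 34 with 622 genes in all, and the model were set before the data were examined, as were all alternatives except array weights and a covariate for the arrays' main pattern of deviation. Lists were tested on the A arrays with camera at a preset correlation of 0.01 between genes, 1 probe set per gene (the one with the highest mean), for lists with at least 5 measured genes. Camera with an estimated correlation and fry were alternatives. Member counts of a list use both array types, with each gene counted once. Genes were named by a rule: on the A arrays, the 8 largest rises and 8 largest falls at 48 h and the 4 largest of each at earlier times, and on the B arrays the 2 largest of each, among probe sets past the threshold with 1 symbol and no overlap of values. Up to 4 members of each list with the largest moderated statistic were added. Members named because a count of 5 or fewer refers to them, and a few genes marked as such in the results, were chosen after their values were seen.

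Tested on simulated arrays with the real means and spreads and 200 changed probe sets at 48 h against 0 h, the model recovered 78% of those changed by a log2 of 1 and 100% of those changed by a log2 of 2 on the A arrays, and 42% and 76% on the B arrays. Of its calls 3.8% and 4.8% were false. The noise was drawn independently for each probe set, without the deviations that probe sets of a real array share. These rates thus describe the model under its own assumptions, and those in the real data may be worse. The alternatives were quantile normalization, median scaling, other pseudocounts and filters, the replicate number as a block, no intensity trend, only the times compared, and each array left out in turn. Figures were drawn with matplotlib 3.10.9.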

Results

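RNA from cultured mouse extraocular muscle, the muscle that moves the eye, was measured at 0, 4, 12, 24 and 48 h on a pair of Affymetrix array types, with 3 arrays per time on each type and 30 arrays in all. The A type carried 22690 probe sets and the B type 22575. The labels do not say which event started the clock, whether replicates were separate cultures, or whether A and B arrays with the same number held the same RNA. P-values therefore measure only the spread between arrays, which may be technical. One B array at 0 h, replicate 1, was titled extraocular muscle but had leg muscle as its source name, and was kept under its title. No leg muscle array was analysed here for comparison. The question of each comparison was how expression at a later time differed from 0 h or from the preceding time. Intensities below are mean ± SD and log2 changes are ± SE, with n = 3 arrays per time, and the number of arrays limits the precision of both.

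The ratio of 3' to 5' signal of the Gapdh control probe sets averaged 0.82 ± 0.03 (SD, n = 3) at 0 h and 0.81 ± 0.02 at 48 h on the A arrays, and 0.81 ± 0.02 and 0.8 ± 0.01 on the B arrays. For Actb the A array means were 1.06 ± 0.07 and 1.05 ± 0.03. Each array's mean correlation with the other arrays of its time, across probe sets, ranged from 0.962 to 0.979 on the A type and from 0.852 to 0.891 on the B type. Probe sets are not independent replicates. The median standard error of a log2 change was 0.179 on the A type and 0.266 on the B type. For 100 probe sets present on both types, the changes measured on the A and B arrays at 48 h correlated across probe sets with Pearson r 0.836 and Spearman rho 0.657. At 4, 12 and 24 h Pearson r was lower, 0.558, 0.664 and 0.666, and Spearman rho was 0.553, 0.636 and 0.653.

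Of 13577 A array probe sets tested, 1030 changed over time in limma's F-test, and 138 of 13507 did so on the B arrays. Among those 1030, the highest mean lay at 48 h for 388, at 24 h for 216, at 4 h for 200, at 0 h for 188 and at 12 h for 38. Without 48 h replicate 1 the A count was 667. The B count fell to 76 without 0 h replicate 1, 79 without 4 h replicate 1, 84 without 24 h replicate 2, and 82, 91 and 74 without 48 h replicates 1, 2 and 3.

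**Figure D1:**
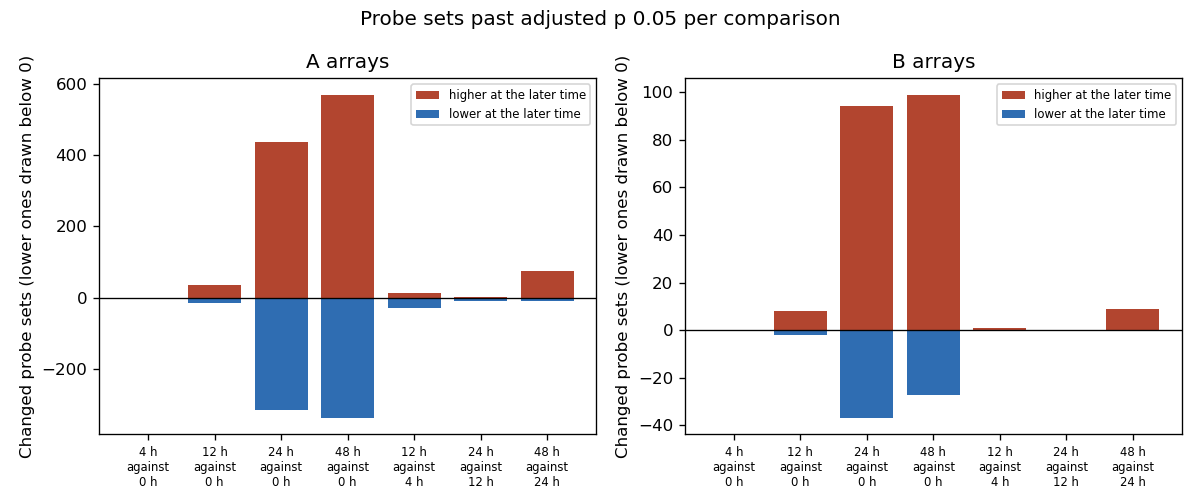
Probe sets past adjusted p 0.05 in limma for each comparison (x axis), drawn as counts above 0 when higher at the later time and below 0 when lower, for A arrays (left) and B arrays (right). On the A arrays 438 were higher and 317 lower at 24 h than at 0 h, and 570 and 339 at 48 h.

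At 4 h, 3 genes were lower than at 0 h on the A arrays. Errfi1, a feedback inhibitor of EGF receptor signalling, fell from an intensity of 1260 ± 434 to 387 ± 96.0 (log2 change -1.63 ± 0.26, limma adjusted p = 0.0311), and its other probe set went the same way. Fos fell from 430 ± 103 to 148 ± 27.5, and Ier2 from 1884 ± 306 to 947 ± 128. Fos and Ier2 belong to the immediate early genes, which respond within minutes to growth factors and handling. Of 25 measured members of that list, 2 fell over all genes tested and 13 adjusted over the list alone, and the median change was -0.49, or -0.32 without 0 h replicate 3. The list's camera adjusted p was 4.95e-15, against adjusted p = 0.0529 with an estimated correlation. Junb (-0.79 ± 0.14, adjusted p = 0.0784) and Egr1 (-1.06 ± 0.20, adjusted p = 0.0905) did not pass. Cyp1a1, singled out after its values were seen, had a mean of 1369 ± 122 at 4 h and 787 ± 66.3 at 0 h, which did not pass (adjusted p = 0.617).

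In all, 4 A array probe sets passed at 4 h, all lower, and 817 had an unadjusted p under 0.05. No B array probe set passed in limma, where 698 had an unadjusted p under 0.05. The A count became 0 without 0 h replicate 1 or 3, 4 h replicate 1 or 24 h replicate 1, and 1 without 4 h replicate 3, 12 h replicate 1 or any 48 h array. It also became 0 with median scaling, with no filter, without the variance trend, with the replicate block and with only the times compared, and 1 B probe set passed without 48 h replicate 2. Over the other settings and the runs without an array, Errfi1 lost its call in 14 of 26, Fos in 15 of 25 and Ier2 in 15 of 26. Camera called 10 of 28 lists at 4 h and none with an estimated correlation. Among these, mitosis genes had 26 of 29 positive changes, with none past limma's threshold and 3 at an unadjusted p under 0.05 (camera adjusted p = 2.05e-05, adjusted p = 0.612 with an estimated correlation). DNA replication genes went the other way, with 5 of 30 positive (camera adjusted p = 7.34e-06, adjusted p = 0.502 with an estimated correlation). Ribosome biogenesis genes had 1 of 21 positive (1.7e-07, and adjusted p = 0.218 with an estimated correlation), and sterol and fatty acid synthesis genes 2 of 21 (7.67e-06, and adjusted p = 0.249 with an estimated correlation).

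At 12 h, a few genes of the contractile apparatus passed as higher than at 0 h. Myoz2, a Z-disc protein, rose from 429 ± 83.2 to 1199 ± 206 (1.45 ± 0.21, limma adjusted p = 0.0141), and Lmcd1 from 90.5 ± 63.6 to 349 ± 83.3. Fhl1 rose by a log2 change of 1.41 ± 0.29. Krtap5-1 rose from 49.9 ± 9.60 to 175 ± 62.1 in a probe set that can cross-hybridize, while its other probe set (log2 change 0.65) did not pass. Of 31 measured sarcomere genes, 4 rose (Actn2, Tnnc2, Myoz2 and Smpx) and 19 did so adjusted over the list alone (camera adjusted p = 3.58e-14, adjusted p = 0.131 with an estimated correlation). The myosin heavy chains Myh7 (1.35 ± 0.22) and Myh8 (1.24 ± 0.26) rose, with 3 other measured chains not past the threshold. In muscle energy metabolism, Pgam2 and Mb rose among 17 genes (camera adjusted p = 4.58e-07, adjusted p = 0.131 with an estimated correlation). Several of these calls were lost in most of the other settings and runs without an array: Smpx and Myh8 in 18 of 26, Mb in 17, Fhl1 in 16 and Pgam2 in 14, and Krtap5-1 in 15 of 25, while Actn2 and Tnnc2 lost theirs in 8.

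The genes with the largest falls at 12 h were Nefm, a neurofilament subunit (-1.61 ± 0.29), Cyp1a1, a cytochrome P450 under control of the aryl hydrocarbon receptor (-1.44 ± 0.22), Alcam (-1.41 ± 0.29, and -1.46 in its other A array probe set, which did not pass) and Vegfc, a lymphatic growth factor (-1.22 ± 0.24). The B arrays had Vegfc falling from 2555 ± 167 to 982 ± 70.5 (log2 change -1.37, and -1.33 in its other probe set, which did not pass), and Dynap from 3760 ± 706 to 1522 ± 206, while Klhl30 rose from 1027 ± 236 to 2654 ± 398. Ifi27 rose from 302 ± 110 to 2033 ± 758 in its probe set with the largest change, whereas its other probe set did not pass (0.44 ± 0.16). Alcam lost its call in 18 of 25 other settings and runs without an array, and Dynap in 16 of 26. Without 0 h replicate 1 of the B arrays, the array with the leg muscle source name, Dynap, Klhl30 and Ifi27 lost their calls and Vegfc kept its own. Without 0 h replicate 2 only 1 B array probe set passed, a lower one, so Klhl30 and Ifi27 lost their calls there too.

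The A arrays gave 50 changed probe sets at 12 h, 34 higher and 16 lower, and the B arrays 10, 8 higher and 2 lower. Median scaling left 4 on the A arrays, 25% of them higher against 68% here. Of the A array probe sets, 6 passed with no filter (50% higher), 5 without the variance trend (20% higher) and none with only the times compared. Without 12 h replicate 3 the A count was 276, and it was 1 and 6 without 0 h replicates 1 and 2, 28 without 4 h replicate 1, 4 without 12 h replicate 1 or 2, 24 and 33 without 24 h replicates 1 and 2, and 20 and 31 without 48 h replicates 1 and 2. The B count was 34 without 12 h replicate 3, 2, 1 and 19 without 0 h replicates 1, 2 and 3, 5 without 4 h replicate 1, 2 and 1 without 12 h replicates 1 and 2, 6 without 24 h replicate 3 and 4 without 48 h replicate 1.

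At 24 h, 15 of 31 sarcomere genes were higher than at 0 h and none lower, though no sarcomere gene was among the 12 A array probe sets that changed directly from 12 h to 24 h. Those that rose against 0 h included Myoz2 (1.98 ± 0.21), Actn2 (1.93 ± 0.25) and Tnnc2 (1.42 ± 0.21), and Csrp3 went from 499 ± 86.1 to 1192 ± 134. The list's camera adjusted p was 4.3e-13, against adjusted p = 0.11 with an estimated correlation. Perinatal myosin Myh8 rose from 388 ± 115 to 1688 ± 500, slow myosin Myh7 from 217 ± 39.2 to 829 ± 248 and embryonic myosin Myh3 from 4996 ± 59.0 to 8675 ± 1780. Of 17 excitation-contraction coupling genes 8 rose, including the calcium channel subunit Cacna1s (1.40 ± 0.23), the calcium pump Atp2a1 (1.08 ± 0.23) and the calcium buffer Casq2 (1.27 ± 0.23), with camera adjusted p = 1.12e-08 and adjusted p = 0.0791 with an estimated correlation. In muscle energy metabolism 7 of 17 rose, among them Cox6a2 (1.75 ± 0.23), Cox8b (1.86 ± 0.31) and Pygm (1.46 ± 0.23), with camera adjusted p = 4.51e-07 and adjusted p = 0.11 with an estimated correlation.

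Single genes with the largest rises at 24 h were Fxyd6, a regulator of the sodium pump (50.5 ± 70.3 to 390 ± 135), Lmcd1 (90.5 ± 63.6 to 708 ± 182), Myzap (2.37 ± 0.48) and the fatty acid transporter Cd36 (2.28 ± 0.47). Those of the B arrays were Ankrd23 (3.01 ± 0.62) and Hoxd13 (2.87 ± 0.54). The largest falls were those of Smoc2, a secreted calcium-binding protein (357 ± 80.6 to 23.0 ± 17.9), Cyp1a1 (787 ± 66.3 to 77.4 ± 4.93), Nefl (-2.43 ± 0.38) and Nefm (-2.38 ± 0.29). Among B array genes 1700012B09Rik (-3.43 ± 0.69) and Rps6ka6 (-2.44 ± 0.45, and -0.46 in its other probe set, which did not pass) fell. Of these B array genes only Hoxd13 kept its call without 0 h replicate 1.

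Several genes of DNA synthesis were lower at 24 h. Of 30 measured, 8 fell and 14 did so adjusted over the list alone, with none rising. They included Pcna (10063 ± 412 to 7303 ± 246), Mcm7 (-0.64 ± 0.14) and the licensing factor Cdt1 (-0.78 ± 0.16). The camera adjusted p was 1.05e-10, and adjusted p = 0.198 with an estimated correlation. Among 12 Id, TGF-beta and BMP targets 5 fell, of which Id1 (-1.28 ± 0.17), Id2 (-1.83 ± 0.25) and Id3 (-1.72 ± 0.17) encode inhibitors of myogenic transcription factors. That list had camera adjusted p = 2.26e-05 and held at adjusted p = 0.039 with an estimated correlation. Smooth muscle and pericyte markers had camera adjusted p = 0.000157 and held at adjusted p = 0.039 with an estimated correlation, and of these Tagln, Pdgfrb, Mcam and Smtn rose among 7 measured. Of the lists tested at 24 h, no other did. Extracellular matrix genes rose in 9 of 29 cases and fell in 1, Timp1. Fbln5 rose by 2.15 ± 0.33, Loxl1 by 1.11 ± 0.14, Nid2 by 1.08 ± 0.14 and Col5a1 by 1.01 ± 0.18 (camera adjusted p = 9.29e-06, adjusted p = 0.0791 with an estimated correlation). In the IGF system Igf1 (1.32 ± 0.26) and Igfbp3 (1.79 ± 0.29) rose among 11 (camera adjusted p = 0.0138, adjusted p = 0.0791 with an estimated correlation), and in sterol and fatty acid synthesis Dhcr7 and Scd2 rose among 21 (camera adjusted p = 6.38e-05, adjusted p = 0.198 with an estimated correlation). In the unfolded protein and amino acid stress list 5 of 17 rose at 24 h, Ddit3, Trib3, Asns, Chac1 and Psat1 (camera adjusted p = 2.26e-05, adjusted p = 0.0791 with an estimated correlation), and at 12 h none passed in limma and 6 had an unadjusted p under 0.05 (camera adjusted p = 0.0046, adjusted p = 0.178 with an estimated correlation). Camera called 15 of 28 lists at 12 h and 15 at 24 h, and with an estimated correlation 0 and 2.

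**Figure D2:**
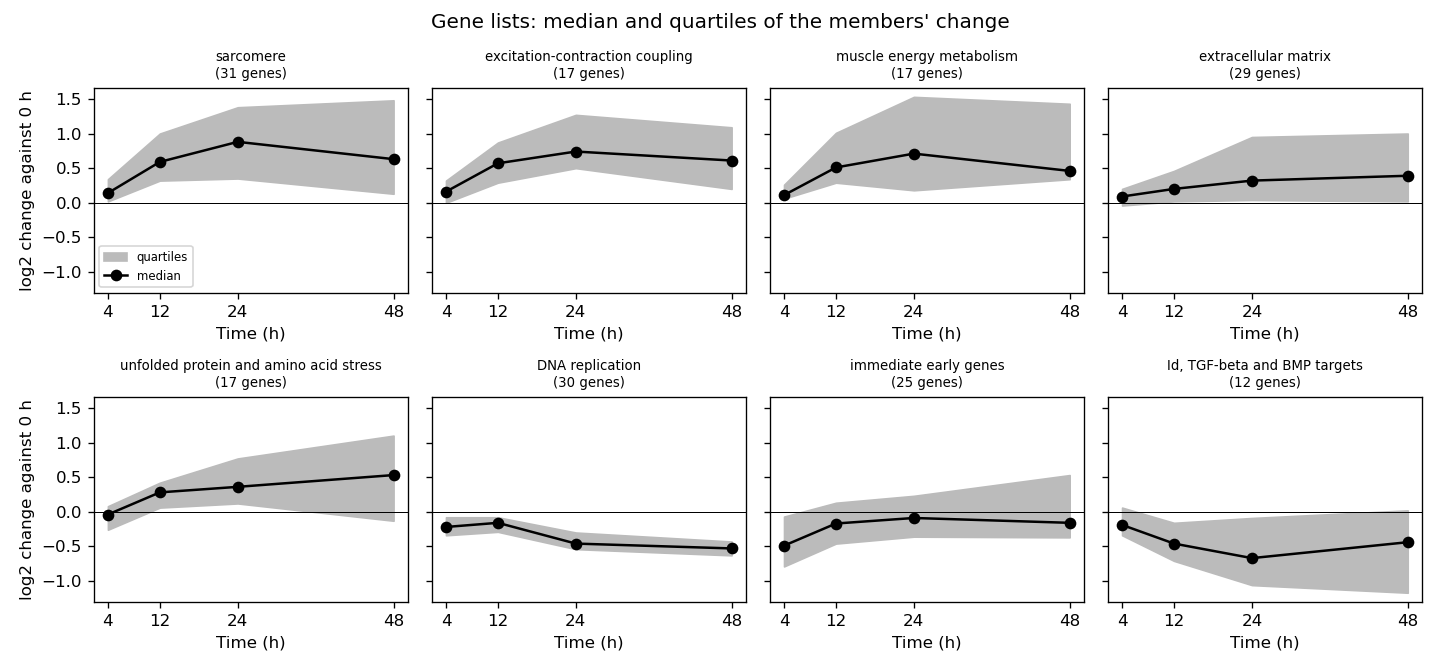
Median (points and line) and quartiles (grey) of the members' log2 change against 0 h (y axis) at each time in hours (x axis), for 8 gene lists. The sarcomere median was 0.59 at 12 h and 0.88 at 24 h, the DNA replication median -0.46 at 24 h and -0.53 at 48 h, and the immediate early gene median -0.49 at 4 h.

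The A arrays gave 755 changed probe sets at 24 h, 438 higher and 317 lower, and the B arrays 131, 94 higher and 37 lower. Of the A array probe sets, 24.3% had non-overlapping values at 0 h and 24 h, where chance gives 10%. The A count was 424 without 0 h replicate 1, 358 without 24 h replicate 1 and 397 without 24 h replicate 2. The B count was 47 without 0 h replicate 1, the array with the leg muscle source name, 81 and 84 without 0 h replicates 2 and 3, and 54 and 24 without 24 h replicates 1 and 2.

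At 48 h, several genes induced by amino acid stress were higher than at 0 h, whereas no endoplasmic reticulum chaperone of the same list was. Trib3, a kinase-like inhibitor induced by ATF4, rose from 99.5 ± 38.1 to 1880 ± 187 (4.09 ± 0.21, limma adjusted p = 6.22e-09). Ddit3, which encodes the stress factor CHOP, rose from 164 ± 43.4 to 1545 ± 207, Atf3 from 27.7 ± 26.0 to 579 ± 168, and Cth, an enzyme of cysteine synthesis, from 125 ± 15.2 to 1248 ± 264. Of 17 measured unfolded protein and amino acid stress genes 8 rose, including Chac1 (2.22 ± 0.18) and the amino acid transporter chain Slc3a2 (1.29 ± 0.17), and 1, Creld2, fell. The list's camera adjusted p was 1.84e-05, against adjusted p = 0.122 with an estimated correlation. Among 14 p53 targets Sesn2 (2.07 ± 0.24), Pmaip1 (1.14 ± 0.22), Aen (0.64 ± 0.13) and Plk2 (0.38 ± 0.11) rose, with camera adjusted p = 0.00819 and adjusted p = 0.186 with an estimated correlation. Plk2 lost its call in 14 of 26 other settings and runs without an array. Sesn2 is also known to be induced by ATF4.

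Other large rises at 48 h were those of Ptx3, a secreted pattern-recognition protein (111 ± 37.2 to 1774 ± 932), Ndrg1 (3.54 ± 0.37, with 4 other probe sets also higher), Dcx, a microtubule protein of migrating neurons (3.32 ± 0.78, with 1 of 2 other probe sets passing), and Fxyd6 (3.17 ± 0.51). Ankrd23 on the B arrays, a muscle ankyrin repeat protein, rose from 56.3 ± 23.6 to 1925 ± 225 and Fam20a from 37.6 ± 20.4 to 697 ± 232. The largest falls were those of Cyp1a1 (787 ± 66.3 to 49.7 ± 13.3), Smoc2 (-3.38 ± 0.47), the transcription factor Atoh8 (313 ± 24.2 to 24.2 ± 12.6) and Rgs4 (-2.81 ± 0.29). Id2 (-2.50 ± 0.25), Tafa5 (-2.44 ± 0.33), Selp (-2.38 ± 0.42) and Sct (-2.34 ± 0.47) followed, and on the B arrays 1700012B09Rik (-3.29 ± 0.69) and Dmp1 (-2.30 ± 0.39). Without 0 h replicate 1 of the B arrays 1700012B09Rik no longer passed, and over all times 8 of 13 calls of named B array genes were lost, none reversing. Leaving out 0 h replicate 2 of the B arrays instead also lost 8 of the 13, so such losses were not particular to replicate 1.

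Several muscle genes were above 0 h at 48 h. Of 31 sarcomere genes 15 rose, led by Myoz2 (2.17 ± 0.21), with camera adjusted p = 3.35e-09 and adjusted p = 0.186 with an estimated correlation. In excitation-contraction coupling 5 of 17 rose (camera adjusted p = 6.78e-05, adjusted p = 0.186 with an estimated correlation), and in muscle energy metabolism 6 of 17 (camera adjusted p = 1.84e-05, adjusted p = 0.186 with an estimated correlation). Acta1 and Myog were singled out after their values were seen. The alpha-actin gene Acta1 measured 12769 ± 494 at 0 h and 13902 ± 1642 at 48 h (0.12 ± 0.14, adjusted p = 0.713). Of 9 myogenic regulators, Mef2c rose (1884 ± 431 to 3153 ± 314) and Myod1 fell (7444 ± 1899 to 4413 ± 648), while Myog measured 10695 ± 3219 at 0 h and 9128 ± 992 at 48 h (adjusted p = 0.719). Of 30 DNA replication genes 10 fell and 23 did so adjusted over the list alone, among them Mcm6 (-1.04 ± 0.23), Mcm7 (-0.78 ± 0.14) and Rrm2 (-0.78 ± 0.14), with camera adjusted p = 2.43e-14 and adjusted p = 0.186 with an estimated correlation. In the mitosis list Cdk1 and Bub1b fell among 29 (camera adjusted p = 4.49e-06, adjusted p = 0.451 with an estimated correlation).

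The Id, TGF-beta and BMP list had 6 of 12 members lower at 48 h, with Id3 at 4068 ± 130 and then 880 ± 230 (camera adjusted p = 3.77e-05 for the list, adjusted p = 0.052 with an estimated correlation). Extracellular matrix genes rose in 11 of 29 cases, with Postn (2.82 ± 0.40) and Fbln5 (2.94 ± 0.33) among them, and Timp2 fell (camera adjusted p = 4.49e-06, adjusted p = 0.122 with an estimated correlation). Of 7 smooth muscle and pericyte markers Tagln (1.10 ± 0.25), Pdgfrb (1.29 ± 0.18) and Mcam (1.33 ± 0.31) were higher (camera adjusted p = 0.00931, adjusted p = 0.123 with an estimated correlation). Immediate early genes went both ways: 5 rose, including Atf3 and Klf4 (1.91 ± 0.22), and 6 fell, including Egr2 (-1.94 ± 0.22) and Junb (-0.94 ± 0.14). Heat shock genes also divided, as the muscle-enriched Hspb2, Hspb3 and Hspb7 rose and Hsph1, Dnajb1, Dnaja1, Hspa8 and Hspd1 fell. In the FOXO and atrophy list Tsc22d3, Txnip and Eif4ebp1 rose and Pdk4 fell from 910 ± 119 to 184 ± 19.6. Oxidative phosphorylation leaned lower at 48 h, with 4 of 24 changes positive and a median of -0.19. Of its members 0 passed limma's threshold and 7 had an unadjusted p under 0.05, with camera adjusted p = 0.000203 and adjusted p = 0.356 with an estimated correlation. Camera called 11 of 28 lists at 48 h and 0 with an estimated correlation.

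**Figure D3:**
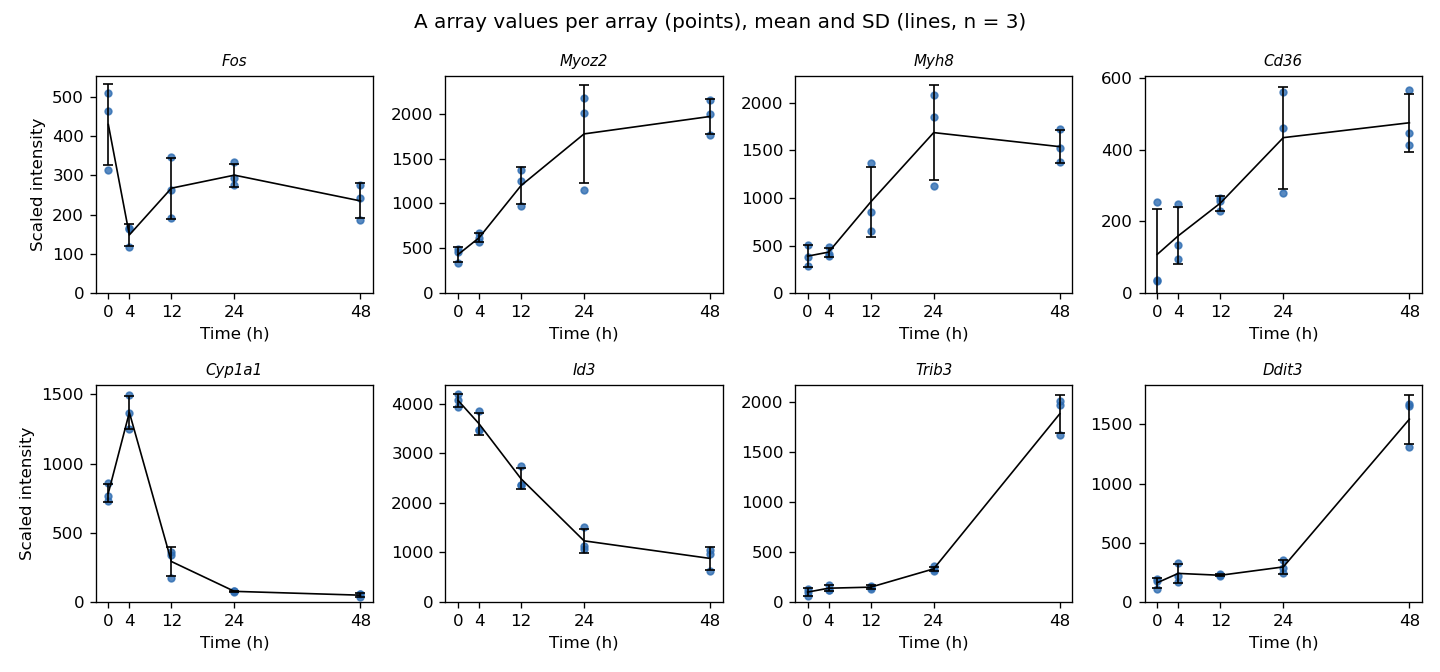
A array scaled intensity (y axis) against time in hours (x axis) for 8 genes, with 1 point per array and lines joining means with SD bars (n = 3). Trib3 averaged 99.5 at 0 h, 332 at 24 h and 1880 at 48 h, and Cyp1a1 787, 77.4 and 49.7.

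The A arrays gave 909 changed probe sets at 48 h, 570 higher and 339 lower, and the B arrays 126, 99 higher and 27 lower. Higher calls were 62.7% of the A array calls but 43.4% under median scaling, and the A count was 526 without 0 h replicate 1, 526 without 48 h replicate 1 and 559 without 48 h replicate 3. Without 0 h replicate 1, the array with the leg muscle source name, the B count was 74.

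Between consecutive times after 4 h, the genes named here were chosen after their values were seen. From 4 h to 12 h 40 A array probe sets changed, 12 higher and 28 lower, and the largest changes were the fall of Cyp1a1 (-2.23 ± 0.22) and the rise of Igfbp3 (2.00 ± 0.29). A single B array probe set passed, also for Igfbp3 (1.18 ± 0.15). From 12 h to 24 h 12 changed, 3 higher and 9 lower (2 and 2 with only the times compared, and 58 and 48 with array weights). Among the 12, those with a symbol were Cyp1a1, Aldh3a1, Gsta4, Ptgr1, Nqo1, Id3 and Blvrb, which fell, and Kdelr3 and Actg2, which rose. No B array probe set passed in limma there, and 566 had an unadjusted p under 0.05. From 24 h to 48 h 85 changed, 74 higher and 11 lower (122, 78 higher and 44 lower, with only the times compared), led by Trib3 (2.44 ± 0.21) and Ddit3 (2.33 ± 0.22), and 9 rose on the B arrays.

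These counts depended on single arrays. From 4 h to 12 h the A count was 173 without 12 h replicate 3, 5, 13 and 11 without 4 h replicates 1, 2 and 3, and 9 and 6 without 12 h replicates 1 and 2. From 12 h to 24 h it was 1 without 12 h replicate 1, 5, 5 and 6 without 24 h replicates 1, 2 and 3, and 21 without 48 h replicate 3. From 24 h to 48 h it was 46 and 36 without 24 h replicates 1 and 2, and 34 and 37 without 48 h replicates 1 and 3. The single B array call from 4 h to 12 h was lost without 4 h replicate 1 or 3 or any 12 h array, and there were 2 without 0 h replicate 1 and 3 without 48 h replicate 2. From 12 h to 24 h, 1 B array probe set passed without 24 h replicate 2 or 3 or 48 h replicate 1.

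Markers of other cell types moved in part. Besides the smooth muscle and pericyte genes, Cd36 rose among 3 adipocyte markers at 24 h and 48 h, and among 7 Schwann and neural markers Nefl and Nefm fell and Tubb3 rose (0.93 ± 0.16 at 48 h). None of 7 fibroblast, 3 endothelial or 4 macrophage and leukocyte markers passed in limma at any time, and at 48 h 3, 0 and 0 had an unadjusted p under 0.05. Adjusted over the list alone, 1 fibroblast marker rose at 12 h and 1 at 48 h. Of 5 head and extraocular muscle regulators Foxc2 fell at 24 h (1299 ± 443 to 567 ± 39.6), and none of 7 limb and trunk patterning genes on the list for these passed in limma, with 2 at an unadjusted p under 0.05 at 24 h and 1 at 48 h, the latter a rise adjusted over the list alone. Hoxd13, a limb patterning gene outside that list, rose on the B arrays at 24 h (2.87 ± 0.54). None of 10 neuromuscular junction genes or 5 interferon response genes passed in limma at any time, with 2 and 1 at an unadjusted p under 0.05 at 48 h, though Ifi27, an interferon-induced gene outside that list, rose in 1 of its B array probe sets at 12 h. Among 9 dystrophin complex genes Capn3 rose at 48 h (1.46 ± 0.26), among 16 adhesion and fusion genes Ncam1 (0.88 ± 0.18) and Cav3 (1.26 ± 0.29) rose, and among 14 cell cycle arrest genes Gadd45a rose (1.36 ± 0.32). In the Notch list of 12, Notch3 rose (0.58 ± 0.16) and Hey1 (-1.79 ± 0.41) and Lfng (-0.67 ± 0.19) fell at 48 h, though Notch3 and Lfng each lost the call in 14 of 26 other settings and runs without an array. Vegfa, Ndrg1 and P4ha1 rose at 48 h among 17 hypoxia and glycolysis genes, P4ha1 losing its call in 16 of those 26, and Vegfc fell among 10 cytokines and chemokines.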

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

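For the named genes and list members, 192 calls were run again under each setting, and each call counts once per setting here. Of 1696 such results under settings chosen beforehand 1497 stayed past the threshold and 199 no longer passed. Under those chosen after seeing the data 381 of 384 stayed. These include the covariate for the arrays' main pattern of deviation, where all 192 stayed. It was taken from the arrays' deviations from their time means, so it cannot alter a log2 change and is no test of stability. With 1 array left out 2478 of 2880 stayed, though most of these left out an array outside the call's own comparison. Without A array 0 h replicate 1, 53 of 179 were lost. None reversed in any of these. The losses were uneven: of 192 calls 122 passed in every run that tested them and 21 were lost in most runs. The filter at the 60th percentile tested only 160 of the 192. Counts moved more, and the cause was not tested unless named. The replicate block left 0, 34, 733 and 886 A array probe sets at 4, 12, 24 and 48 h against 0 h and 934 over time, and 0, 7, 103, 122 and 109 on the B arrays. Arrays with the same number did not deviate together (median correlation of deviations 0 and -0.003, with 6 and 5 of 15 arrays closest to their own number), so the numbers were not taken to pair samples. With median scaling, A counts were 0 at 4 h and 4 at 12 h against 0 h and 55 from 24 h to 48 h, with 70.9% higher against 87.1%, and the B count at 12 h was 5. With no filter, which adds dim probe sets, the A arrays gave 0 at 4 h, 6 at 12 h, 20 from 4 h to 12 h and 5 from 12 h to 24 h, and the B arrays 4 at 12 h and 87 at 24 h. A filter at the 60th percentile gave 16 at 12 h and 7 from 4 h to 12 h on the B arrays. Without the intensity trend the A arrays gave 0 at 4 h, 5 at 12 h, 22 from 4 h to 12 h and 7 from 12 h to 24 h, and the B arrays 1 at 12 h, 46 at 24 h, 77 at 48 h, 0 from 4 h to 12 h and 51 over time. With only the times compared, which leaves fewer arrays in the fit, the A arrays gave 0 at 4 h, 0 at 12 h, 7 from 4 h to 12 h, 4 from 12 h to 24 h and 122 from 24 h to 48 h (63.9% higher against 87.1%), and the B arrays 1 at 12 h, 45 at 24 h, 5 from 4 h to 12 h and 4 from 24 h to 48 h.

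Alternatives chosen after seeing the data raised the A array counts of probe sets, but not every B array or list count. Array weights gave 10, 595, 1528 and 2396 on the A arrays at 4, 12, 24 and 48 h against 0 h, 580, 106 and 1345 between consecutive times and 4361 over time, and on the B arrays 26 at 12 h and 11 from 4 h to 12 h, with 126 at 48 h and 9 from 24 h to 48 h as before, and 13 lists instead of 15 at 12 h and at 24 h. The covariate for the arrays' main pattern of deviation, which held 26.5% of the A arrays' deviation variance, gave 11, 228 and 1256 at 4, 12 and 24 h against 0 h, 134, 38 and 225 between consecutive times and 1818 over time, and on the B arrays 17 at 12 h and 6 from 4 h to 12 h. It left each log2 change as it was and took up part of the spread, so a rise in these counts follows largely from its construction. Lists called at 4, 12, 24 and 48 h were 0, 0, 2 and 0 with an estimated correlation, and 1, 7, 12 and 11 with fry. Fry asks whether a list moves, not whether it moves more than other genes.

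Leaving out each array in turn, A counts ranged from 0 to 5 at 4 h, 1 to 276 at 12 h, 358 to 846 at 24 h and 526 to 1006 at 48 h against 0 h, from 5 to 173, 1 to 21 and 34 to 100 between consecutive times, and from 667 to 1348 over time. B counts ranged from 0 to 1, 1 to 34, 24 to 148 and 74 to 147 against 0 h, from 0 to 3, 0 to 1 and 6 to 11 between consecutive times, and from 74 to 168 over time. Lists called ranged from 7 to 14, 10 to 16, 13 to 16 and 10 to 12. The arrays whose omission moved a count by over 1.5 times stand beside each count in the results. Probe sets below an intensity of 16 made up 11.06% to 15.79% of an A array and 3.38% to 4.58% of a B array, where changes are least certain.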

Other observations

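The tests of a brief rise at 0 h, of chaperones, of single-array noise and of a replaced 4 h sample were chosen after the results were seen. The lists of NRF2 and aryl hydrocarbon receptor targets, NF-kB targets and amino acid supply genes were written from textbook knowledge after single genes had been seen to move. Their tests leave out the genes that prompted them and 5 further measured members whose values had already been looked at. The second group was taken out after a first run, in which the deciding adjusted p-values were 0.0114, 0.73 and 0.00252. P-values of added lists were adjusted over 6 tests, those of the lists set beforehand over 28 at each time. The same threshold was thus easier to pass for an added list, and its adjusted p cannot be set beside theirs.

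Cyp1a1, Nqo1, Gsta4, Gclm and Ptgr1, which encode detoxifying and glutathione enzymes, were all lower at 24 h than at 0 h. Of 17 other measured targets of NRF2 and the aryl hydrocarbon receptor, 8 fell at 24 h and none rose: Gclc, Txnrd1, Srxn1, Gsr, Tiparp, Ahrr (-1.53 ± 0.24), Aldh3a1 (-1.30 ± 0.25) and Pgd (-0.96 ± 0.18). The median was -0.41, and the list held with an estimated correlation (camera adjusted p = 0.0209 over 6 tests of added lists). At 48 h 6 fell and the adjusted p was 0.0436. Unadjusted, camera with an estimated correlation gave p = 0.00696 at 24 h and p = 0.0218 at 48 h. The excitation-contraction coupling list, with an unadjusted p = 0.00989 at 24 h in that test, did not hold over 28 lists. At 4 h the means of Cyp1a1 (1369 against 787), Ahrr (277 against 195), Gclm (1728 against 1273) and Gclc (2145 against 1621) were above those at 0 h without passing in limma, and all 4 genes fell from 4 h to 12 h. What lowered the group was not tested. Nfkb2 and Nfkbia also fell at 24 h (a further Nfkb2 probe set did not pass), whereas none of 8 other NF-kB targets passed limma's threshold (adjusted p = 0.823), so the fall was not shown to extend to that group.

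Psph, Pck2, Cth and Mthfd2 on the A arrays, and Aldh1l2 on the B arrays, were higher at 48 h than at 0 h. Of 15 other genes of amino acid supply (serine and one-carbon enzymes, tRNA charging, amino acid transport) 11 rose at 48 h and none fell, including Aars (0.82 ± 0.11), Sars (0.99 ± 0.12), Slc1a4 (1.37 ± 0.15), Slc7a5 (1.45 ± 0.15) and Aldh18a1 (1.31 ± 0.16). The median was 0.80 and the list held with an estimated correlation (camera adjusted p = 0.00846 over 6 tests). At 24 h 5 of the 15 rose, and the list did not hold with an estimated correlation (adjusted p = 0.0898). With Trib3, Ddit3, Chac1, Asns and Psat1 these are known ATF4 targets, so an amino acid response in the 48 h cultures is a candidate explanation, although neither ATF4 activity nor amino acids were measured. Mthfd1, Cbs and Slc38a2 did not pass, nor did the Shmt1 probe set counted here, although another Shmt1 probe set fell (-0.85 ± 0.23, limma adjusted p = 0.0348).

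Of 17 unfolded protein and amino acid stress genes 8 were higher and 1 lower at 48 h, and a rise of the whole list was not established (camera adjusted p = 1.84e-05, adjusted p = 0.122 with an estimated correlation). The list's median, 0.53 as analysed, was 0.43 in the weaker of the other scalings and 0.48 in the weakest run without a 48 h array, which argues against scaling and a single 48 h array. A general unfolded protein response at 48 h would raise endoplasmic reticulum chaperones too. At that time the 8 chaperone and folding members had a median of -0.17 (quartiles -0.27 and 0.04), against 1.13 for 8 amino acid response members. An earlier response is not excluded. From 4 h to 12 h the members Sdf2l1 (0.84 ± 0.17) and Creld2 (0.73 ± 0.14) rose in limma, and Creld2 fell from 24 h to 48 h (-0.69 ± 0.14). No other of these 8 passed between consecutive times after 4 h. Within the list, the rise at 48 h thus lay in the members grouped here as amino acid response genes, a name that does not show which stress raised them. The 8 do not stand for all folding genes. Ero1a, which encodes an endoplasmic reticulum oxidase and was singled out after its values were seen, rose from 24 h to 48 h in limma. Its probe sets past the threshold gave 1.19 ± 0.17, 1.13 ± 0.23 and 1.10 ± 0.17. This division of the list was made after the results were seen. What triggered the rise was not tested, and time in culture and medium depletion stay open, since the labels do not say whether medium was changed.

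Of 25 immediate early genes 2 fell at 4 h, Fos and Ier2, whose calls were lost in 15 of 25 and 15 of 26 other settings and runs without an array, and a fall of the group was not established (median -0.49, camera adjusted p = 4.95e-15, adjusted p = 0.0529 with an estimated correlation). The median was -0.50 in the weaker of the other scalings and -0.32 in the weakest run without a 0 h array (replicate 3), which argues against scaling and against a single 0 h array. Handling or a medium change at 0 h could have raised these genes briefly, in which case they would stay low later. The list's median was -0.17 at 12 h (quartiles -0.46 and 0.13), -0.09 at 24 h (-0.36 and 0.23, 2 rose and 3 fell) and -0.16 at 48 h (-0.37 and 0.53, 5 rose and 6 fell), with members going both ways, so this cannot be told apart from a change that set in after 0 h, because the labels do not say what happened at 0 h. All later times share the 0 h arrays.

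Along the change from 0 h to 24 h (0 for the mean of the 0 h arrays, 1 for that of the 24 h arrays, over the probe sets changed at 24 h), 12 h replicate 3 lay at 0.432 on the A and 0.485 on the B arrays, and the other 12 h arrays between 0.641 and 0.686. Deviations from each time's mean correlated between A and B arrays of the same time and number (Pearson r = 0.962, permutation p = 0.00024, adjusted p = 0.00048; Spearman rho = 0.957, permutation p = 8e-04, adjusted p = 8e-04; two-sided, permuted within times, 15 samples, 2 relations), with r 0.927 without the 2 farthest and 0.923 without the 12 h arrays (permutation p = 0.00135), which argues against noise of single arrays. The smallest gap to the other 12 h arrays was 0.166 under other scalings, and the smallest gap to the highest 4 h array was 0.233, against a 4 h sample in its place. A and B arrays of the same number may thus have held the same RNA, with that 12 h sample less advanced. Whether the culture lagged or was collected earlier stays open.

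Splits of the same arrays into other groups of equal size bear on each count. For change over time, the real grouping was the only 1 of 100 splits to reach its count on either type. It gave 1030 against at most 55 on the A and 138 against at most 11 on the B arrays, so chance among arrays does not account for these. Chance differences between cultures could not be excluded, because the labels do not say whether replicates were separate cultures. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. On the A arrays the real counts at 4, 12, 24 and 48 h against 0 h were 4, 50, 755 and 909 and the highest others 1, 0, 1 and 1, and between consecutive times 40, 12 and 85 against 0, 1 and 2. On the B arrays they were 0, 10, 131 and 126 against 4, 3, 1 and 0, and 1, 0 and 9 against 0, 1 and 1. All 10 splits gave at least the real count of 0 for the B arrays at 4 h and from 12 h to 24 h, and only the real split did for the other probe set counts. Lists called by camera were 10, 15, 15 and 11 against at most 10, 11, 10 and 10 in other splits, and at 4 h 2 of the 10 splits gave as many. The list counts differed far less from those of other splits than the probe set counts at 24 h and 48 h against 0 h did. Every other split of 3 against 3 mixes arrays of both times, so a real change enters the spread and lowers the probe set count. Camera sets a list against other genes and need not be lowered in the same way. The contrast between list and probe set counts therefore does not compare the strength of their evidence. The B array probe set counts at 4 h (0 against 4) and from 12 h to 24 h (0 against 1) lay below those of another split.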
